A study of Mus musculus with 4 samples.

How the data were processed

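MNase-seq was made from SCC089 mouse embryonic stem cells, 2 libraries after mild and 2 after extensive digestion, grouped by the labels of each sample. The deposited files list aligned single reads, 1 per line, with position, strand and a mapping quality score from 10 to 37; per the submitters' processing notes, BWA, SAMtools and mm9 were used, and versions and parameters are not given in the sources used here. No 2 reads of a library shared position and strand. Single reads give fragment length only indirectly, from the distance between strands. No read had a mapping score below 10, so repeated sequence is measured only in part, and 1 read per position caps the count of very dense bins.

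The libraries held 14083388 and 5550607 (mild) and 14423395 and 5450356 (extensive) reads, of which at least 99.7% lay on chromosomes 1 to 19 and X. Each read was moved 75 bp from its 5' end towards the fragment centre and counted in bins of 5 kb. The median tested bin held 26 and 10 reads in the mild and 30 and 11 in the extensive libraries. Bins with at least 10 reads in 2 libraries were tested with voom and empirical Bayes moderation in limma 3.58.1 (R 4.3.3), scaled to total reads, without covariates, with Benjamini-Hochberg adjustment at 0.05. The ratio is mild over extensive and is relative to each library's total. Intervals for read shares are exact Clopper-Pearson intervals at 95%. For bins with 0 reads in a group, folds are bounds against 3 reads over the group. The tests of chromosomes, bins and peak slopes, their alternatives and the rule for named bins were chosen before the data were examined; what was added later is named as such. That rule took the 5 highest and 5 lowest log2 fold changes among called bins whose groups did not overlap.

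Chromosome density was the share of reads per megabase covered by a read in any library, over the library mean. Differences between groups of single values were tested by exact permutation, two-sided. Distances between 5' ends up to 2000 bp were counted on each strand, smoothed over 20 bp, and the repeat length was the slope of peak position on peak number. A damped cosine with periods from 150 to 240 bp, fitted from 120 to 1000 bp with a decay length of 400 bp, was added after the data had been seen, with SE from leaving out each chromosome. Narrow sites were windows of 200 bp with at least 8 times the mean and a Poisson probability below 1e-05, merged up to 3000 bp, outside the densest 1% of bins. They were read out in the libraries of the other sequencing run.

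On simulated counts with 200 bins changed between mild and extensive digestion, the fit over 393812 bins recovered 4% of 2-fold and 55% of 4-fold changes with 2 false calls. The dispersion of these counts was set to 0.02 and not taken from the data. Far fewer bins were changed than were called in the data, which makes the adjustment stricter. The simulation therefore gives neither the power nor the error rate of the fit on the data. The period fit was tested on simulated nucleosome arrays and erred by at most 0.5 bp. The strength of their periodic signal was not matched to the libraries, where the fitted cosine had a size of 1.41% to 2.54% before its decay. That error is therefore not the accuracy of the fit on the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.

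Alternatives covered scaling, read minimum, thinning, replicate block, limma-trend, leaving out each library, read shift, mapping quality and bin size. The gene table at hand is of another genome build, GRCm38, so promoters, gene lists, sequence classes, profiles at gene starts, genome features and GC content were not analysed here, and bins carry no gene names.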

Results

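Micrococcal nuclease (MNase) cuts DNA that is not wrapped around histones, so light and heavy digestion of the same nuclei release different parts of the genome. Nuclei of mouse embryonic stem cells carrying a Nanog-GFP reporter, grown without feeder cells in leukaemia inhibitory factor, were digested mildly or extensively. DNA of mononucleosome size was taken from a gel and sequenced. The aim named for the series was a genome-wide map of open chromatin, and the comparison its design implies is mild against extensive digestion. There were 2 mild and 2 extensive libraries. The mild libraries held 14083388 and 5550607 aligned reads, and the extensive libraries 14423395 and 5450356. In each group replicate 1 was the deeper library. Read names placed both replicate 1 libraries on one sequencing run and both replicate 2 libraries on another, so each ratio could be taken within 2 runs. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. All positions are on mm9.

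The share of reads by chromosome differed between the digestions, with chromosome 11 highest and the X chromosome lowest under mild relative to extensive digestion. Read density on chromosome 11 was 1.37 ± 0.00964 times the library mean under mild and 1.21 ± 0.00429 times under extensive digestion (SD, n = 2), a difference of 12.5%. Chromosome 17 was 10.1% higher and chromosome 19 was 6.43% higher. On the X chromosome the density was 0.346 ± 0.0136 under mild and 0.419 ± 0.00507 under extensive digestion (SD, n = 2), a log2 ratio of -0.27. It was lower in both runs, with log2 ratios of -0.22 and -0.33. Chromosome 3 followed at -0.18 and chromosome 1 at -0.11. Chromosomes 11 and 19 are known as gene-rich. Of the 20 chromosomes, 10 had a higher density under mild digestion in both runs and 10 a lower density in both. The groups did not overlap on 19 of them, where chance gives 33.3% for a single chromosome. Chromosome densities are shares of 1 total and not independent, so 1 difference between libraries can separate many of them at once. With 2 libraries against 2, a two-sided exact permutation test cannot go below p = 0.333. The smallest Benjamini-Hochberg value over the 20 chromosomes was 0.351, so no chromosome passed a threshold.

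**Figure D1:**
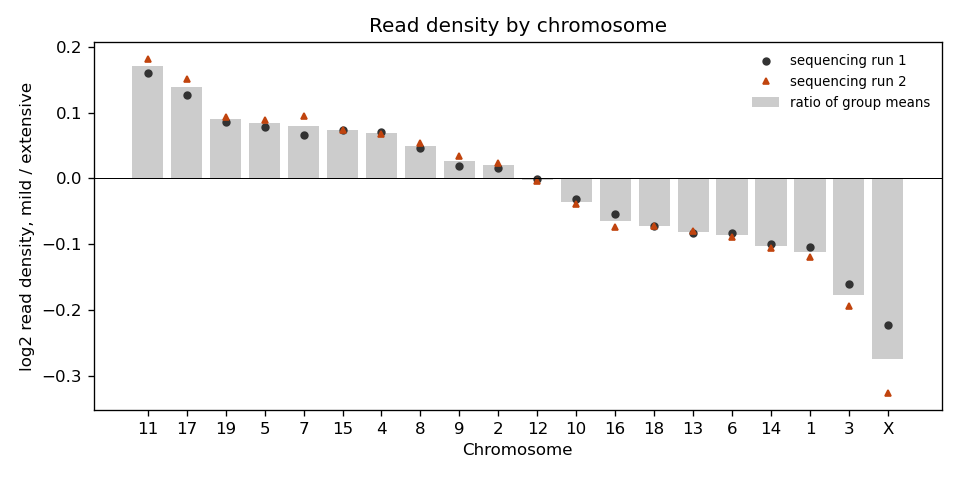
Log2 ratio of read density, mild over extensive, for each chromosome in order of size of the ratio. Bars show the ratio of the group means and points the ratio in each of the 2 sequencing runs; chromosome 11 is highest at 0.17 and the X chromosome lowest at -0.27.

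In windows of 5 kb, mild digestion raised the read share of 28287 bins and lowered that of 13592, out of 413805 tested (limma-voom, Benjamini-Hochberg adjusted p under 0.05). The bins that rose had a median fold of 1.79, and those that fell were lower by a median of 2.46-fold. Chromosome 11 had the largest share of bins that rose, 12.3%, followed by chromosome 17 with 10.9% and chromosome 4 with 9.91%. Chromosome 3 had the lowest share of the autosomes, 2.80%. Of the bins with any read, 91.7% could be tested on chromosome 11, the highest share, and 80.8% on chromosome 14, the lowest of the autosomes. On the X chromosome 30.8% could be tested, because its bins held fewer reads. Its shares of 1.88% that rose and 0.495% that fell, of 9503 bins, are therefore not comparable with those of the autosomes. Autosomes differed in read density too, so their order may partly follow read counts. Chromosome 11 had 1.37 (mild) and 1.21 (extensive) times the library mean, and chromosome 3 had 0.806 and 0.912 times. Outside the densest 1% of bins, 24167 rose and 13575 fell, of 408749 tested. Of the bins that rose, 98.6% were higher in both runs, and of those that fell, 96.7% were lower in both runs; these bins were picked from the same libraries.

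The bins with the highest ratios were spread over 5 chromosomes. The bin on chromosome 3 from 5860001 to 5865000 held 399 and 190 reads under mild and 84 and 33 under extensive digestion. That is 31.4 ± 4.17 against 5.96 ± 0.162 RPM (reads scaled to library total; SD, n = 2), with a limma log2 fold change of 2.34 ± 0.15 (SE) and an adjusted p of 4.86e-19. This bin is among the densest 1% of bins, which the results on wider regions, narrow sites and fitted periods leave out. The bin on chromosome 8 from 74760001 to 74765000 held 65 and 28 reads against 12 and 6, with a log2 fold change of 2.40 ± 0.35 (SE, limma adjusted p = 3.23e-06). On chromosome 1 from 5100001 to 5105000 the log2 fold change was 2.29 ± 0.37, and on chromosome 2 from 34965001 to 34970000 it was 2.28 ± 0.37. In the limma-voom fit the highest log2 fold change, 2.62 ± 0.60 (SE), was that of a sparse bin on chromosome 12 from 52755001 to 52760000, with 37 mild and 9 extensive reads. It was the lowest of the 5 with limma-trend, at 1.84, and with the replicate block, at 1.90. Without extensive replicate 1 it went to 0.61, the chromosome 2 bin to 1.37 and the chromosome 1 bin to 3.58, and these and the chromosome 8 bin lost their call (limma adjusted p from 0.139 to 0.733). The chromosome 12 bin also lost it without extensive replicate 2 (limma adjusted p = 0.315).

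The 5 bins with the lowest ratios had no read in either mild library. The first, on chromosome 5 from 6345001 to 6350000, held 19 and 11 reads under extensive digestion (limma adjusted p = 0.0127). Against a floor of 3 reads over the mild group it was at least 9.88-fold lower. Those on chromosome 6 from 141955001 and from 138885001 were at least 9.22-fold and 8.24-fold lower. The bins on chromosome 10 from 82010001 and on chromosome 4 from 146015001 were at least 8.24-fold and 7.91-fold lower. With 0 mild reads, a bin was tested only if both extensive libraries held at least 10 reads. That filter favours high counts in the shallower replicate 2, so the bounds cover the mild side only. The chromosome 4 bin held 12 and 12 extensive reads, or 1.52 ± 0.971 RPM (SD, n = 2). With a minimum of 20 reads in 2 libraries, all 5 bins went untested. All 5 lost their call with limma-trend (adjusted p from 0.244 to 0.358), without mild replicate 1 (limma adjusted p from 0.107 to 0.194), without extensive replicate 1 (0.196 to 0.213) and without extensive replicate 2 (0.178 to 0.237). With the 5' end not moved by 75 bp, the bins on chromosome 6 from 141955001, on chromosome 10 and on chromosome 4 lost it too (limma adjusted p of 0.0858, 0.0782 and 0.171). Their log2 fold changes were then -3.41, -3.50 and -2.80, so their calls depend on that shift. Across the genome 106 bins had at most 1 mild read and at least 20 extensive reads, and 0 bins had the reverse.

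The number of called bins depended on single libraries and on depth. Without extensive replicate 1, 6 bins rose and 0 fell, with 69767 at an unadjusted p under 0.05; without mild replicate 1, 6455 rose and 30 fell; without mild replicate 2, 5372 fell; and without extensive replicate 2, 14283 rose and 2695 fell. With every library thinned to the shallowest, limma-voom and limma-trend each called 0 bins, with 40997 and 47553 bins at an unadjusted p under 0.05. Limma-trend called 16213 higher and 6279 lower, and the number that fell was 24530 without a read minimum and 2294 with a minimum of 20 reads. At 20 kb, scaling to total reads gave 16975 bins higher and 30186 lower, and median-of-ratios scaling 25577 higher and 14138 lower.

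The ratio agreed better between the runs over wider regions. These regions and the sites described after them were chosen after the data had been seen. With the densest 1% of bins left out, the correlation of the log2 ratio between runs, across regions that are not independent replicates, was 0.380 at 5 kb, 0.645 at 20 kb, 0.863 at 100 kb and 0.951 at 500 kb. Wider regions hold more reads, and the read minimum was raised with width. Less counting noise alone can raise this correlation, so the rise does not show the scale of the difference. The 5% of 100-kb regions with the highest ratio in run 1 had a median log2 ratio of 0.60 in run 2, and 99.8% of them were above 0 there. The 5% with the lowest ratio had a median of -0.73 in run 2. Neighbouring regions were alike: across the runs, the correlation was 0.737 at a distance of 0.1 Mb, 0.433 at 1 Mb and 0.123 at 5 Mb.

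Some long stretches of one sign in both runs covered whole parts of chromosomes. Most stretches were short: scaled to total reads, the median length was 0.2 Mb for higher and 0.2 Mb for lower ones. With scaling to total reads, the longest with more reads under mild digestion lay on chromosome 11 from 114.9 to 121.6 Mb, with median log2 ratios of 0.53 and 0.56 in the 2 runs. It was followed by chromosome 4 from 136.1 to 142.1 Mb, with 0.52 and 0.54, and chromosome 17 from 26.9 to 32.7 Mb, with 0.50 and 0.51. With that scaling the longest with fewer reads lay on chromosome 16 from 59.6 to 78.3 Mb, with medians of -0.43 and -0.54. Others lay on chromosome 1 from 108.7 to 120.2 Mb and on chromosome 14 from 108.1 to 118.3 Mb. There were 609 stretches of at least 1 Mb, 188 higher and 421 lower when scaled to total reads. The split, the limits and the order of the stretches rested on that scaling. With each run centred on its median region, 325 were higher and 299 lower. The longest higher stretches then lay on chromosome 5 from 110.5 to 126.3 Mb, on chromosome 4 from 130.3 to 143 Mb and on chromosome 11 from 112.6 to 121.7 Mb. The longest lower ones lay on chromosome 6 from 75.4 to 81.8 Mb and on chromosome 2 from 39.2 to 44.8 Mb, and the chromosome 16 stretch was no longer among the 3 longest. When the regions scaled to total reads were put in random order 100 times, the highest number was 81 and the longest stretch 2.4 Mb.

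**Figure D2:**
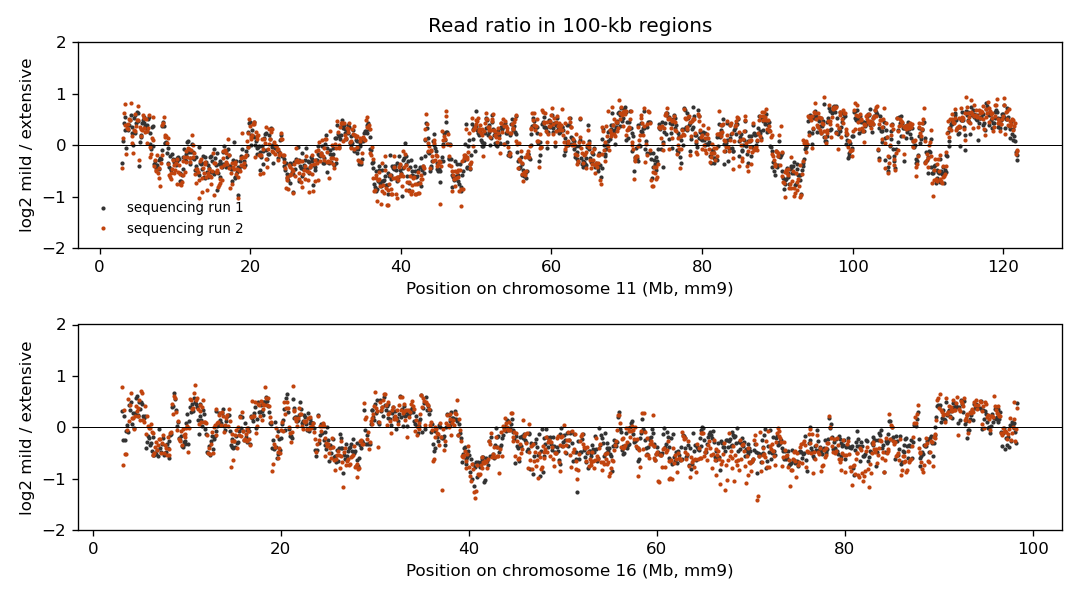
Log2 ratio of reads, mild over extensive, in 100-kb regions along chromosomes 11 and 16 (position in Mb, mm9), scaled to total reads. Each point is a region in 1 of the 2 sequencing runs; with that scaling, the stretches from 114.9 to 121.6 Mb on chromosome 11 and from 59.6 to 78.3 Mb on chromosome 16 lie on opposite sides of 0.

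Reads of mild digestion also gathered at narrow sites. Windows of 200 bp needed at least 8 times the mean density and a count past the Poisson limit. Together these came to 10 reads in the replicate 1 libraries and 6 in the replicate 2 libraries. In replicate 2 the Poisson limit was the stricter one, so site counts are compared within runs only, and overlaps between runs rest on unlike thresholds. There were 94100 sites in mild replicate 1 and 54114 in mild replicate 2, against 13536 and 7197 in the extensive libraries of the same runs. As many reads as each library held, placed at random, gave 52 and 564 sites for the mild libraries, and 42 and 449 for the extensive ones. These reads were spread evenly over each chromosome, while the libraries were denser in some regions than in others. Denser regions reach the limit by chance more often, so these counts can understate the number of chance sites. Read out in the other run, the sites of mild replicate 1 had 5.80 times the genome mean under mild and 2.72 times under extensive digestion, a ratio of 2.13. The sites of mild replicate 2 gave 5.42 and 2.71 times, a ratio of 2.0. Sites found in the extensive libraries also held more mild reads in the other run, by 1.56 and 1.30 times. The flanks there, 1000 to 1200 bp away, were also denser under mild digestion, so these ratios are not those of the sites alone. Centre over flank there was 3.23 (mild) against 1.98 (extensive) at mild replicate 1 sites and 3.02 against 1.93 at mild replicate 2 sites. At the extensive sites it was 3.57 against 2.63 (replicate 1) and 2.62 against 2.38 (replicate 2). Of the mild replicate 2 sites, 30.9% lay within 200 bp of a site of mild replicate 1, against 3.87% after moving them by 10 kb. Of the extensive replicate 2 sites, 10.5% lay as near to a site of extensive replicate 1 (0.639% after moving them) and 20.7% to a site of mild replicate 1 (3.25%), which has more sites.

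**Figure D3:**
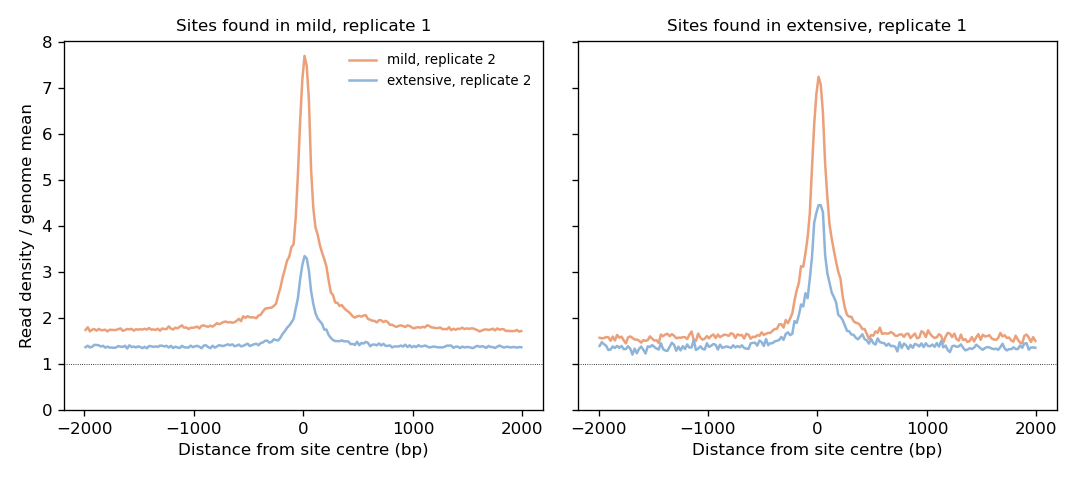
Read density over the genome mean in the replicate 2 libraries, by distance in bp from the centre of sites found in mild replicate 1 (left) and extensive replicate 1 (right). Lines are 1 library each; within 100 bp of the centres on the left, mild digestion has 5.80 and extensive digestion 2.72 times the mean.

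The distance between reads on the same strand carries the spacing of nucleosomes. Its curve had 8 and 7 peaks in the extensive libraries, the first at 350 and 792 bp. It had 3 and 4 peaks in the mild libraries, where the first came only at 1134 and 1142 bp. The slope of peak position on peak number, the measure chosen beforehand, was 210 ± 72.1 bp under mild and 157 ± 49.4 bp under extensive digestion (SD, n = 2; exact permutation p = 0.667), and differed by less than the spread between replicates. With so few peaks, found so late, it is not a usable measure of spacing in the mild libraries. Nor is it in extensive replicate 2, where the slope was 122 bp, so neither group mean of the slope is a spacing. A period fitted to the curve without the densest 1% of bins, a measure added after the data had been seen, was 179.5 ± 2.95 and 185.0 ± 2.81 bp in the mild libraries (SE over chromosomes). In the extensive libraries it was 191.5 ± 1.21 and 188.0 ± 3.61 bp. The mild group was lower by 7.5 bp, and the groups did not overlap, which chance gives in 33.3% of cases (exact permutation p = 0.333). The difference was -4.75 bp without mild replicate 1, -4.5 bp with a longer decay length in the fit and -14 bp between opposite strands. With all bins kept, it was -1 bp, but the replicate 2 fits then had an SE of 24.5 bp (mild) and 40.7 bp (extensive); in replicate 1 the periods were 184 ± 4.75 and 194.5 ± 2.83 bp (SE). The most frequent distance between opposite strands was 141 and 158 bp under mild digestion. It was 122 and 96 bp under extensive digestion (exact permutation p = 0.333). The value of 96 bp is below the median read length of that library, so it is not a fragment length. Regions of 100 kb were also ranked by the ratio of the other run. In the 4922 lowest and 4921 highest, the extensive distances were 103 and 141 bp (replicate 1) and 96 and 144 bp (replicate 2). The mild distances were 142 and 135 bp, and 162 and 158 bp. A difference in fragment length does not follow from these distances. The same 75-bp shift was used for all libraries. Close pairs of reads were more frequent under mild digestion: pairs 20 to 100 bp apart were 2.01 ± 0.0434 times as frequent as far pairs, against 1.49 ± 0.0585 times under extensive digestion (SD, n = 2; exact permutation p = 0.333).

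**Figure D4:**
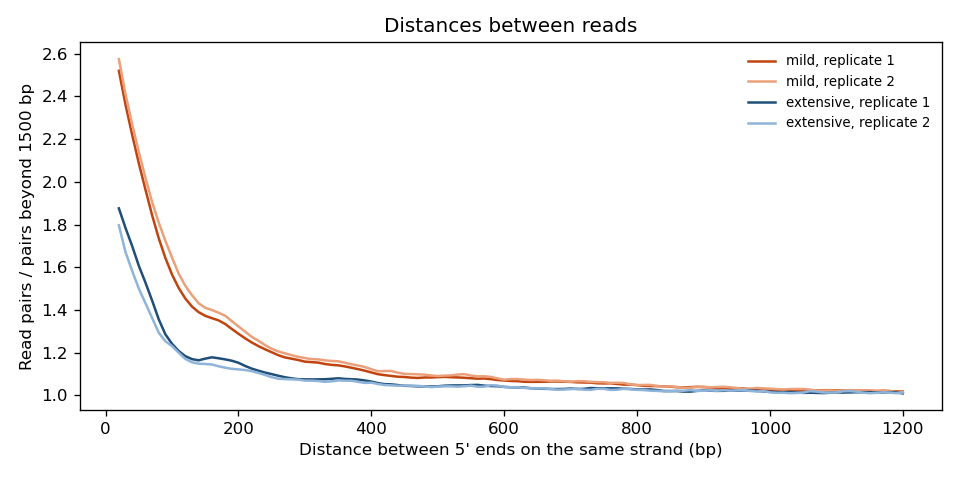
Frequency of read pairs by the distance between their 5' ends on the same strand, in bp, over the frequency beyond 1500 bp, without the densest 1% of bins. Lines are the 4 libraries; both mild libraries lie above both extensive libraries at short distances, with means of 2.01 and 1.49 at 20 to 100 bp.

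Reads from the mitochondrial genome, which carries no nucleosomes, were more frequent under mild digestion. They made up 214.5 and 199 RPM in the mild libraries, with exact 95% intervals of 207 to 222 and 187 to 211. In the extensive libraries they made up 44.6 and 99.99 RPM, with intervals of 41.2 to 48.2 and 91.8 to 109. The ratio was 4.81 in run 1 and 1.99 in run 2. The intervals cover counting error only, and the exact permutation test gave p = 0.333.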

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

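Reads on the Y chromosome and on unplaced contigs lay outside the comparisons of the results and were counted separately, and both were found in each library. The Y chromosome held 175 ± 16.8 RPM under mild and 234 ± 7.06 under extensive digestion (SD, n = 2), with mild over extensive ratios of 0.781 and 0.711 in the 2 runs. Unplaced contigs held 1921 ± 167 and 2348 ± 254 RPM (SD, n = 2), with ratios of 0.807 and 0.831. They include contigs assigned to the Y chromosome, so the 2 differences are not separate. Those contigs held 663 ± 192 RPM under mild and 937 ± 236 under extensive digestion (SD, n = 2). Their ratios were 0.723 and 0.683, although the groups overlapped. No explanation of either difference was tested.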

How the results depend on the processing

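The fitted period and the settings that combine 2 choices were added after the data had been seen. The counts of called bins depended on depth and on single libraries. With every library thinned to the shallowest, 0 bins rose and 0 fell by limma-voom (40997 at an unadjusted p under 0.05) and by limma-trend (47553), and 1 rose and 0 fell with the replicate block; limma's prior degrees of freedom went from 63.5 to 3.80, and the cause was not tested further. Leaving out 1 library gave 6 (without extensive replicate 1) to 19553 (without mild replicate 2) bins that rose and 0 to 5372 that fell; the lone library is then assumed to vary like the others. Limma-trend called 16213 and 6279. Without a read minimum, 24530 fell, and with a minimum of 20 reads 2294 fell. With scaling to total reads, at 20 kb 16975 rose and 30186 fell, and at 1 kb 30160 rose and 354 fell. Median-of-ratios scaling moved the median log2 ratio at 20 kb from -0.20 to -0.03, where 25577 rose and 14138 fell, and at 1 kb from 0.34 to -0.04, where 3318 rose and 145 fell. At 1 kb without a read minimum, 10397 rose and 4356 fell. At 5 kb median-of-ratios scaling gave 33048 and 10874. Under that scaling more bins rose than fell at each width. With the replicate block, 32564 rose and 16302 fell, of which 28144 and 11673 were called without it. The replicates of one number, which shared a sequencing run, deviated together with a correlation of 0.0774 across bins. With only 2 pairs, the main fit and the permutation tests did not pair the libraries by run, while the ratios given per run did. The read shift, the mapping quality minimum and the limit of 1 read per position, which removed no read, kept both counts within 1.5 times. For the named bins, 85 of 125 values kept their call, 40 did not, and 0 changed direction; 25 more had no value, as the bin missed the read minimum (6 in each thinned setting, 7 with 20 reads). Of 24 values for chromosomes 3, 11, 17 and X, 23 moved by less than the spread between runs, and chromosome 17 went from 0.14 to 0.11 without the densest bins. The tallies for named bins and chromosomes both include the limit of 1 read per position, which removed no read and could not move a value. The slope difference of 52.9 bp moved by less than the spread between replicates in each setting tried; leaving out 1 library gave 1.88 to 104 bp. The fitted period differed by -1 bp with all bins kept, where the replicate 2 fits had SEs of 24.5 and 40.7 bp, and by -14 bp between opposite strands. GC correction, the promoter, gene list, sequence class, gene start and genome feature results, and edgeR were not run.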

Other observations

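The tests of the narrow sites, of the densest bin and of a single run for the X chromosome were chosen after the result was seen. The densest bin of the genome lay on chromosome 17 from 39980001 to 39985000. It held 671 ± 250 RPM under mild and 169 ± 77.6 under extensive digestion (SD, n = 2), with ratios of 4.35 and 3.79 in the 2 runs. The bin next to it had 3.98 times the RPM under mild digestion. The bin was singled out after its values were seen. Of 32 bins with over 20 times the median density, others lay on chromosome 2 from 98500001, near the start of chromosomes 9 and 11, and near the end of the X chromosome. The densest 1% of bins held 4.24% and 4.72% of mild reads and 2.51% and 2.76% of extensive reads.

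Many genomic copies placed on 1 reference copy could raise the density of such a bin. The median log2 ratio of the other 31 dense bins was 0.30 (SD 0.50), against 1.99 in the densest bin, but the copy number of these bins was not measured, so the comparison decides nothing about copies. Undoing the limit of 1 read per position gave a log2 ratio of 2.45, but that calculation raises the ratio of any bin with more mild reads, so it decides nothing about the limit. A difference in how this sequence is digested stays open and untested.

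For the narrow sites of mild digestion, chance clusters of reads as an account of the sites as a set are argued against by the other run. The mild density at the centres there, averaged over all sites, was at least 3.02 times that 1000 to 1200 bp away. An average can rest on part of the sites, so chance clusters at some of them stay open. Complete emptying of the sites as a set by extensive digestion is argued against too: the extensive density at the centres, averaged over all sites, was at least 1.93 times that of the flanks. The ratio of centre to flank was lower there than under mild digestion. Partial loss, and complete loss at some of the sites, therefore stay open. What the sites hold was not tested.

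The lower density of the X chromosome under mild digestion kept a log2 ratio of -0.26 without the densest 1% of bins, so a few dense bins elsewhere do not account for it. It was at most -0.22 in either run, so 1 run alone does not account for it. Base composition may still account for the log2 ratio of -0.27 and cannot be told apart from chromatin here, since no genome of the build was at hand.

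A hypothesis written before its test held that regions with more reads under mild digestion have closer nucleosome spacing. Regions of 100 kb were ranked by the ratio of the other run. In the single library with a usable fit at both ends of that ranking, extensive replicate 1, the period was 4.5 ± 3.59 bp longer in the 4921 highest than in the 4922 lowest regions (SE). Fits in the other libraries were not usable, with an SE of over 20 bp or a period at the edge of the range tried. The second limit was set after the fits were seen and removed mild replicate 1, where the difference was -63 bp. The hypothesis stays undecided.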
